A study of Mus musculus with 10 samples.

How the data were processed

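Total RNA was extracted with Trizol from 5 tissues of adult female C57BL/6 mice, and biotin-labelled cRNA made from 10 µg of it was hybridised to Affymetrix arrays following the maker's expression manual of 2001, per the labels. Each tissue has 1 array on each of 2 chips, A and B, so there are 10 arrays. The deposited values are intensities on a linear scale and in whole numbers. Values below 0 show that a signal had been subtracted in the authors' processing, but not whether it was background or another signal. Between 17.1% and 38.8% of the values of an array are below 0. The mean of each array after trimming 2% at each end lies between 500.8 and 501.5, so the deposited intensities had been scaled to a common level. The software, its version and calls of presence or absence are not given in the sources used here. The medians of the deposited columns of chip A are 193 for pancreas, 219 for muscle, 143 for liver, 158 for hypothalamus and 173 for the adipose-labelled sample, and those of chip B 149, 144, 93, 100 and 122. For pancreas, muscle, liver and hypothalamus groups were taken from the title, which names the same tissue as the source label. For the adipose arrays the source label names white adipose tissue and the title a preconfluent state, and the label of the source was used for the group.

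Gene names came from a table of platform annotation, with symbols updated by gene identifier from a table of the mouse assembly GRCm38.p6, used for names only. Of 6584 probe sets on chip A, 61 were controls, 5541 had 1 gene, 197 several and 785 none. Of 6595 on chip B, 61 were controls, 2001 had 1 gene, 27 several and 4506 none. A probe set with several genes or none has no name here, and 5532 and 1993 had a symbol in the mouse table, for 6123 genes in all. Values of the chips were compared by level only for probe sets present on both, as the repeat of the hybridisation.

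Controls were left out, each array was divided by its 2% trimmed mean and multiplied by the mean of the 5 trimmed means of its chip, and values under the floor were set to the floor, which is the median of the 5 array medians. The floor was 175 on chip A and 123 on chip B. A probe set was called selective for a tissue where its value was at least 4 times the highest of the other 4 tissues, and shared by a pair where the lower of the 2 was at least 4 times the highest of the other 3. With 1 array per tissue no test was made across samples and no p-value is given. The 28 gene lists were fixed from textbook markers. A gene can be in several lists, so results of lists that overlap are not independent of each other. Fast fibre genes and most slow fibre genes are also in the contractile or energy lists. Some genes of fatty acid synthesis are also in the white adipocyte list. A gene was represented by its probe set with the highest rank of mean log2 value within its chip, and the called genes of a list are counted by it. A list's value in a tissue is the median over its genes of the log2 value minus the mean log2 value of the other 4 tissues, with its percentile among 10000 random lists of the same size matched on mean value in 10 bins. Correlations were taken across probe sets on floored log2 values within a chip and averaged over the chips. The scaling, the floor, the 4-fold rule, the lists, the rule for named genes and the alternatives listed first below were chosen before the data were examined.

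The rule for named genes took, per tissue, the 10 called genes with the largest fold whose next-highest tissue lay above the floor, the 4 genes with the largest fold from each list of the tissue's own cells, 2 from every other list, the 3 genes with the largest fold in each of the 4 pairs of tissues that shared most, 17 genes fixed for the adipose-labelled sample, and 5 reference genes. Of the 17, Cfd and Ccnb1 had no probe set under their name. Alb, Pdia4, Sec11c, Ccna2 and Cd3e are exceptions, chosen after their values were seen. Of 97 named genes called for a tissue, 23 had other probe sets, and for 14 of these another was called for the same tissue, with a value above noise for 12. For 3, Klk1b9, Tpm3 and Klc1, none was highest there, and of these Klc1 had a probe set highest elsewhere and above noise. Some named probe sets are of family design and may bind messages of related genes. They include those of Klk1b5, Klk1b9, Myl1, Myl2, Tnni2, Cox6a2, Cox8b, Cyp3a11, Sst, Stmn1, Fabp4, Pgd and Col1a1. Those of Top2a, Igfbp4, Gnb2, Actb, Gapdh and Ppia are of this design too.

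The spread of values below 0 differed between arrays, so a bound on noise was added after the data were seen: the size of an array's 1st percentile. A fold is given as the tissue's value over the highest, among the other 4 tissues, of the value or of that array's bound, with "at least" where the bound or an unmeasured value sets it, and no fold is given where this is under 1. Calls were also counted with the sign of a tissue's values turned, which noise symmetric about 0 would match. These counts exceeded all calls for pancreas, muscle and the adipose-labelled sample. The values below 0 were thus not symmetric noise there, and the counts do not estimate the share of calls made by noise. The steps were tested on simulated arrays of 13057 probe sets, in which some probe sets were raised in 1 tissue from at least 2 times the floor. Their background noise was normal and sized by each array's noise bound. The real noise need not have that shape, so the shares and counts that follow hold for the simulated arrays and need not carry over. Of 50 raised 2-fold 0 were called, of 50 raised 8-fold 32, of 50 raised 16-fold 46 and of 50 raised 32-fold 50. Among unchanged probe sets 396 were called for pancreas, 178 for muscle, 8 for liver, 0 for hypothalamus and 10 for the adipose-labelled sample. With the own value required to exceed the noise bound these were 143, 108, 8, 0 and 10.

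The alternatives chosen before were the values as deposited, scaling by the 75th percentile, quantile normalization, floors at the 25th and 75th percentiles, folds of 2 and 8, the mean of the other tissues as reference, leaving out probe sets of family or relaxed design (identifiers ending in f, r, i or g), leaving out the adipose-labelled sample, and averaging all probe sets of a gene. Alternatives added after seeing the data required values above the noise bound, used the noise bound as floor, scaled arrays by their hybridisation spikes (bacterial and phage transcripts added to each sample), or left out the pancreas arrays. Calculations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.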

Results

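Messenger RNA of 5 tissues of adult female C57BL/6 mice was measured on Affymetrix one-colour arrays: pancreas, muscle, liver, hypothalamus and white adipose tissue. Each tissue was hybridised once to chip A, with 6584 probe sets, and once to chip B, with 6595, giving 10 arrays. There were no replicates, so no difference below has a test or an error between animals, and the number of arrays limits the precision. The adipose arrays carry a source label of white adipose tissue and a title that names a preconfluent state, and they are called the adipose-labelled sample here. The question was which genes each tissue held at levels above the other 4. A probe set was called selective where its intensity was at least 4 times that of the highest other tissue, with low values raised to a floor of 175 on chip A and 123 on chip B. Of 13057 probe sets, 467 were called for pancreas, 241 for muscle, 277 for liver, 258 for hypothalamus and 119 for the adipose-labelled sample. The noise bound of an array, the size of its 1st percentile, was 1166 for pancreas, 1065 for muscle, 295 for liver, 258 for hypothalamus and 390.1 for the adipose-labelled sample on chip A, and 2608, 1640, 792, 649.5 and 918 in the same order on chip B. Folds are given as "at least" where they are set against such a bound.

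**Figure D1:**
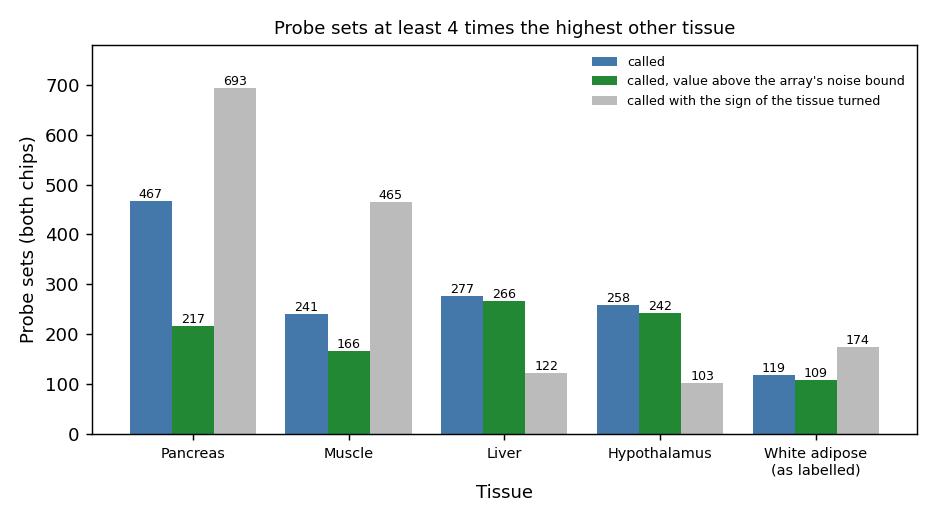
Bars count the probe sets of both chips that were called selective for each tissue, those whose value also exceeded the noise bound of their array, and those called when the sign of the tissue's values was turned, on a linear axis. Pancreas had the most calls, 467, but 217 above its noise bounds, against 266 for liver and 242 for hypothalamus.

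Genes of digestive enzymes and of other proteins that acinar cells secrete were high in pancreas. Prss2, a trypsinogen, read 193067 in pancreas, at least 118-fold above the other 4 tissues, and Amy2a5, a pancreatic amylase, read 168212, at least 103-fold above them. Rnase1, a secreted ribonuclease, reached 168491 (at least 103-fold) and the elastase Cela2a 158083 (at least 96.4-fold). Of the 23 measured genes of the list of acinar enzymes and secretory proteins, 21 were called for pancreas, 20 of them above the noise bound, and the list's median lay 7.42 log2 units above the mean of the other 4 tissues, at percentile 100 of 10000 random lists. Tff2, a trefoil peptide, was at least 54.2-fold higher, a second elastase, Cela1, at least 52.9-fold, Zg16, a protein of zymogen granules, at least 40.9-fold, and Spink1, a trypsin inhibitor, at least 30.0-fold. Klk1b5 and Klk1b9, kallikreins read by probe sets designed for a gene family, were 62.0-fold and at least 20.3-fold higher, while the other probe set of Klk1b9 was not above noise in pancreas. Dazap1, an RNA-binding protein, was at least 20.2-fold higher and Chst2, a sulfotransferase, at least 6.84-fold. Genes of the secretory pathway and endoplasmic reticulum were also high: 22 of 28 had their highest value in pancreas, 4 were called and the median was 1.90 (percentile 100). Besides Pdia4 and Sec11c, which were named after their values were seen, Creld2, a protein of the endoplasmic reticulum, was at least 5.41-fold higher and the co-chaperone Dnajc3 at least 1.95-fold. Ribosomal protein genes had a median of 1.14 (percentile 100), with 35 of 46 highest in pancreas and none called, and the median was 0.79 with 75th percentile scaling, 0.76 with quantile normalization and 0.11 without probe sets of relaxed design. The islet list did not stand apart as a whole, with a median of 0.00 (percentile 57.3) and 2 of 18 genes called for pancreas, while 5, among them Chgb, Scg2 and Sst, were called for hypothalamus. Its member Ins2, which encodes insulin, read 16498, at least 10.1-fold above the other tissues, with its other probe set called but below noise, and Gcg, which encodes glucagon, read 757, below the noise bound. Of 6 duct genes, Muc1, a mucin, was called for pancreas, at least 4.16-fold higher, and the duct list's median was -0.12 (percentile 44.2). Among 765 probe sets above noise in every tissue the pancreas arrays lay 0.54 log2 units above the mean of the others, or 0.19 with 75th percentile scaling. Muscle lay 0.35 above (0.12), and liver at -0.44 (-0.049), hypothalamus at -0.30 (-0.21) and the adipose-labelled sample at -0.14 (-0.061). The ribosomal medians are to be read with these shifts in view. The selection asks for higher values on arrays with higher noise bounds, those of pancreas and muscle, so it may itself make part of the shifts. Against the 467 calls there were 693 with the sign of the pancreas values turned, and 396 of unchanged probe sets in simulated arrays, 143 of them above noise. The 467 calls included 217 above the arrays' noise bounds, 91 probe sets were called where the noise bound of each array was used as its floor, and 67 with arrays scaled by the hybridisation spikes.

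Muscle was set apart by the contractile apparatus and by fast fibre genes. All 9 measured fast fibre genes were called, with a median 8.04 log2 units above the mean of the other 4 tissues, and 15 of 18 contractile genes were called, with a median of 7.16 (both percentile 100). Atp2a1, the calcium pump of the sarcoplasmic reticulum of fast fibres, read 126228, at least 48.4-fold above the other tissues, and Ckm, the muscle creatine kinase, read 176723, at least 67.8-fold above them. The fast troponins Tnnt3 and Tnni2 were at least 65.4-fold and 51.6-fold higher, the fast myosin light chain Mylpf at least 39.5-fold, and Actn3, the actinin of fast fibres, at least 55.8-fold. Skeletal actin, Acta1, was at least 62.7-fold higher in muscle, Myl1, another myosin light chain, at least 53.3-fold, and Myom1, a protein of the M band, at least 5.06-fold. Slow fibre genes were present as well, with 5 of 6 called and a median of 5.89 (percentile 100). Among them, Tnnc1, the slow troponin C, was at least 18.8-fold higher, the myosin light chains Myl3 and Myl2 at least 14.2-fold and 7.47-fold, and Tpm3, a tropomyosin, at least 10.8-fold, although a second Tpm3 probe set read -961 in muscle. Of 28 genes of energy and calcium handling, 14 were called (median 3.24, percentile 100). They included the glycolytic enzyme Eno3 (at least 33.6-fold), the calcium buffer Pvalb (at least 31.9-fold), Pygm, which breaks down glycogen (at least 62.4-fold), myoglobin, Mb (at least 31.6-fold, with its other probe set below noise in muscle), and the calcium release channel Ryr1 (at least 8.53-fold). Nuclear genes of oxidative phosphorylation were shifted less, with 37 of 47 highest in muscle, 2 called and a median of 1.13 (percentile 100). That median stayed above 0 under the scalings run for the lists, which did not include scaling by spikes. The called members were Cox6a2 and Cox8b, cytochrome oxidase subunits, at least 9.93-fold and 12.6-fold higher. The brown adipocyte list had its highest median in muscle, 1.01 (percentile 98.5), and the median was -0.060 without probe sets of relaxed design. Its 2 called genes of 6 were Cox8b and Fabp3, a fatty acid binding protein that was 4.90-fold above hypothalamus. Both are also members of the list of muscle energy and calcium handling, so they are not separate evidence of brown fat cells. Of the 241 muscle calls, 166 had a value above the noise bound of the muscle array, and 411 probe sets were called when the pancreas arrays were left out. Turning the sign of the muscle values gave 465 calls against 241, and unchanged probe sets of simulated muscle arrays gave 178, of them 108 above noise.

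Liver held the genes of plasma proteins and of hepatic metabolism. Of 50 measured plasma protein genes, 41 were called (median 4.60), of 19 genes of the urea cycle, gluconeogenesis and amino acid breakdown, 14 (median 5.33), and of 38 bile acid, lipid and xenobiotic genes, 24 (median 4.64), each list at percentile 100. Apoh, a plasma glycoprotein, read 23012 in liver, at least 8.82-fold above the other tissues (its other probe set was called but below noise), and Cyp3a11, a cytochrome P450 of drug metabolism, read 24789, at least 9.50-fold above them. Both Cyp3a11 probe sets are designed for a gene family. The protease inhibitors Pzp and Serpina1a were at least 16.7-fold and 7.11-fold higher, the corticosteroid carrier Serpina6 at least 8.34-fold, the pentraxin Crp at least 6.30-fold, and Pon1, an esterase carried on high density lipoprotein, at least 12.8-fold. Enzymes of amino acid breakdown and the urea cycle followed, with Hpd, of tyrosine breakdown, at least 13.3-fold higher, Tdo2, of tryptophan breakdown, at least 8.39-fold (at least 2.01-fold by its other probe set, not called), Arg1, an arginase, at least 9.93-fold, and Otc at least 7.71-fold. Fbp1, of gluconeogenesis, was at least 7.43-fold higher. Among genes of drug and bile acid handling, Cyp2d26 read 18663 in liver and at most 128 elsewhere, the esterase Ces1c was at least 11.7-fold higher, Cyp2c29 at least 10.9-fold, and the bile acid transporter Slc10a1 at least 7.32-fold. Alb, albumin, was not called: it read 26266 in pancreas, 18122 in liver and 8226 in muscle on chip B, and was named after its values were seen. Of the 277 liver calls, 266 had a value above the noise bound, and with the sign of the liver values turned there were 4 calls against 153 on chip A, but 118 against 124 on chip B.

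The hypothalamus was marked by neuropeptides and by genes of neurons. Oxt and Avp, which encode oxytocin and vasopressin, read 11298 and 10766, at least 9.69-fold and 9.23-fold above the other 4 tissues. Of 19 measured neuropeptide genes, 9 were called (median 2.44), and of 44 neuron genes, 22 (median 2.26), both lists at percentile 100. Sst, which encodes somatostatin and is also made in islets, was at least 3.47-fold higher in hypothalamus. In pancreas it read -508, where a signal under the noise bound of 2608 would not be seen. The granule protein Scg2 was at least 3.97-fold higher, and the related Chgb and Scg5 at least 1.97-fold and 4.56-fold. Gad1, which makes the transmitter GABA, was at least 3.16-fold higher, Syp, of synaptic vesicles, at least 3.69-fold, the surface protein Thy1 at least 5.89-fold, and Sncb, a synuclein, at least 6.55-fold. The microtubule regulators Stmn3 and Stmn1 were at least 8.30-fold and 2.98-fold higher, but the other Stmn3 probe set was not called, at 3.83-fold above pancreas. Resp18 was at least 9.91-fold higher and Tspyl4 at least 8.27-fold. Klc1, a kinesin light chain, was at least 4.09-fold higher by its called probe set, but none of its 3 other probe sets was highest in hypothalamus. Glial lists were shifted less. The astrocyte list had a median of 0.97 (percentile 100) with 3 of 20 genes called: Ptgds, a prostaglandin synthase, was at least 5.84-fold higher and S100b at least 1.66-fold, while Fabp7 reached 1042, under the noise bounds of pancreas and muscle. The connexin Gjb6 was called by a probe set of chip A, at least 1.23-fold higher, but not by that of chip B, which represents it in the list and read 2082 in hypothalamus and 832 in pancreas. The oligodendrocyte list had a median of 0.56 (percentile 96.5) with 3 of 9 called: the myelin gene Mobp was at least 6.29-fold higher (at least 1.51-fold by its other probe set, not called) and Cldn11 at least 1.47-fold, while Mog read 712, under the bounds of pancreas and muscle. The pituitary list was not raised in hypothalamus, with a median of 0.00 (percentile 82.4) and no gene called. Its highest median was in pancreas, 0.57 (percentile 97.9), where Fshb read 965, below the noise bound. Of the 258 calls (103 with the sign of the hypothalamus values turned), 242 lay above the noise bound of the array, and 47 probe sets were called where the noise bound of each array was its floor. The turned sign gave 4 calls against 126 on chip A and 99 against 132 on chip B. With the floor at the 75th percentile the neuron median was 0.41, the neuropeptide median 0.94 and the astrocyte median 0.0037.

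The adipose-labelled sample carried the genes of lipid-storing fat cells and of their hormones. Adipoq, which encodes adiponectin, read 16860, at least 14.5-fold above the other tissues, Retn, resistin, 15100 against 1379 in pancreas, and Lep, leptin, 2871, at least 2.46-fold above the others. Of 42 white adipocyte genes, 16 were called and 29 had their highest value here, with a median of 3.30 (percentile 100). The fatty acid binding protein Fabp4 was at least 15.0-fold higher, the hormone-sensitive lipase Lipe at least 14.9-fold, the lipid droplet protein Cidec at least 7.71-fold, Adig at least 4.03-fold, and Pparg, the regulator of fat cell formation, at least 1.44-fold. Lipid synthesis was raised, with 5 of 13 genes called and a median of 2.90 (percentile 100), among them Acly, which makes acetyl-CoA from citrate (at least 4.13-fold), and Pgd, which supplies NADPH (at least 6.95-fold). Some genes of this list, such as Acly, are also in the white adipocyte list. The desaturase Scd1 read 13928 here and 18360 in liver, and lipoprotein lipase, Lpl, 10295 here and 19582 in muscle by its bright probe set, so neither was called, and the second Lpl probe set was below noise in all 5 tissues. Abcd2, a peroxisomal transporter, was at least 1.27-fold higher and the proteoglycan Srgn at least 1.22-fold.

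Genes of connective tissue and macrophages were also high in the adipose-labelled sample, and those of cell division were not. Of 55 genes of preadipocytes, fibroblasts and matrix, 35 had their highest value here and 11 were called, with a median of 2.10 (percentile 100). Col15a1, a basement membrane collagen, read 3503 here and 240.2 in pancreas, and Postn, a matrix protein, was at least 1.10-fold higher. Col3a1 on chip B was 2.97-fold above pancreas, and its chip A probe set was also highest here. Col1a1 was 2.76-fold and 2.19-fold above muscle by 2 probe sets, and another read 1394 here against 1717 in muscle. Vim, vimentin, was 3.41-fold above pancreas. Dlk1, a preadipocyte gene, read 36.2 here, below the noise bound, and 634 in hypothalamus. The macrophage list had a median of 1.09 (percentile 100), and its called members Csf1r and Mrc1, receptors of macrophages, read 1758 and 1745, above the array's noise bound of 918 but under that of pancreas. With the floor at the 75th percentile the macrophage median was 0.041. The endothelium list had a median of 0.47 (percentile 99.9) with no gene called. Krt19, a keratin and the called member of the epithelium list, read 1140 here, under the pancreas bound. The cell division list had a median of -0.049 (percentile 53.1) with no gene of 54 called here. Pcna and Mki67, genes of dividing cells, read 577 and 348, below the noise bound, both Top2a probe sets were negative, and Cdk1 read 426 against 1864 in muscle, where it was called. In the other tissues this list had medians of 0.00 in pancreas, 0.00 in muscle, -0.26 in liver and -0.0066 in hypothalamus. Its other called members were Stmn1 in hypothalamus and, in pancreas, Ccna2, named after its values were seen, and Rrm2, of nucleotide synthesis, at 2028; both were below the noise bound, and none of the 3 other Rrm2 probe sets was called. Of the 119 calls for the adipose-labelled sample (174 with the sign of its values turned), 109 lay above its noise bound, and 32 probe sets were called where the noise bound of each array was its floor. The turned sign gave 14 calls against 59 on chip A and 160 against 60 on chip B.

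**Figure D2:**
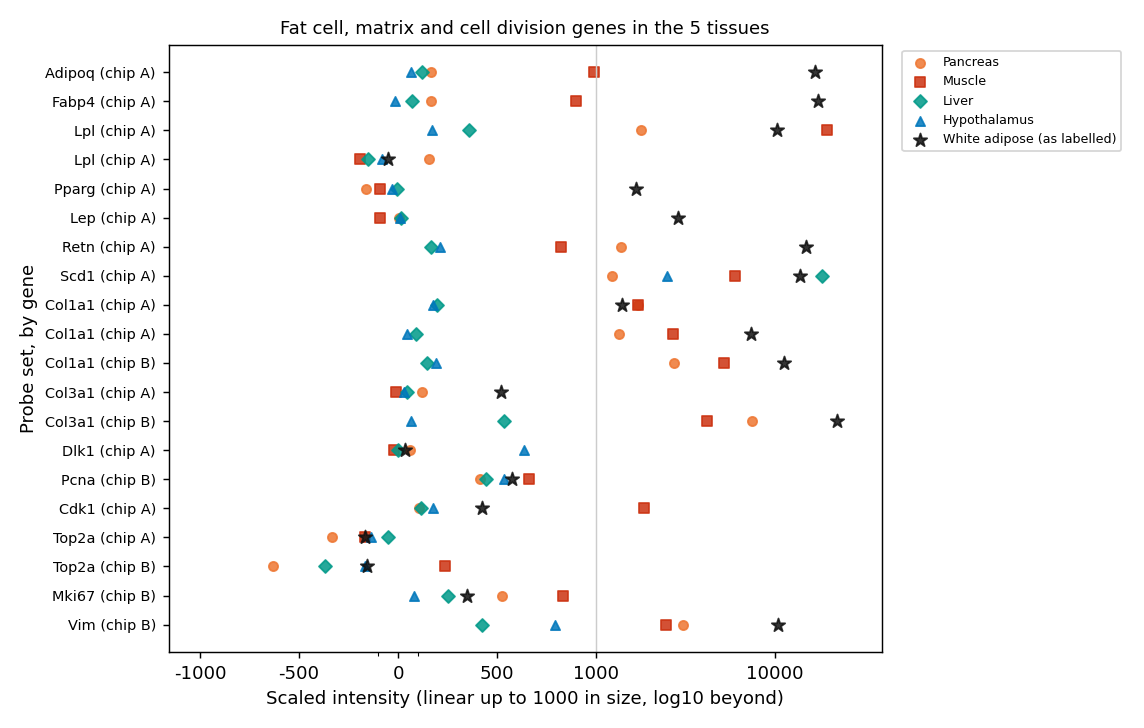
Each symbol is the scaled intensity of a probe set in 1 tissue, on an axis that is linear up to 1000 in size and logarithmic beyond, with the tissues told apart by colour and shape. Adipoq, Fabp4, Lep and Retn lie far to the right in the adipose-labelled sample alone, while its values for Pcna, Mki67 and Top2a lie among those of the other tissues.

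Lists of blood and epithelial cells had few called genes. The lymphocyte list had medians between -0.26 in hypothalamus and 0.00, and its called members were Thy1 in hypothalamus, which neurons also express, Cd52 in liver, which read 787, and in pancreas Cd3e, below the noise bound and named after its values were seen. The red blood cell list was highest in pancreas, at 0.43 (percentile 83.2), with no gene called. The list of mammary and other epithelium was highest in pancreas, at 0.80 (percentile 99.8), with no gene called there, and was 0.49 with 75th percentile scaling and 0.17 without probe sets of relaxed design.

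**Figure D3:**
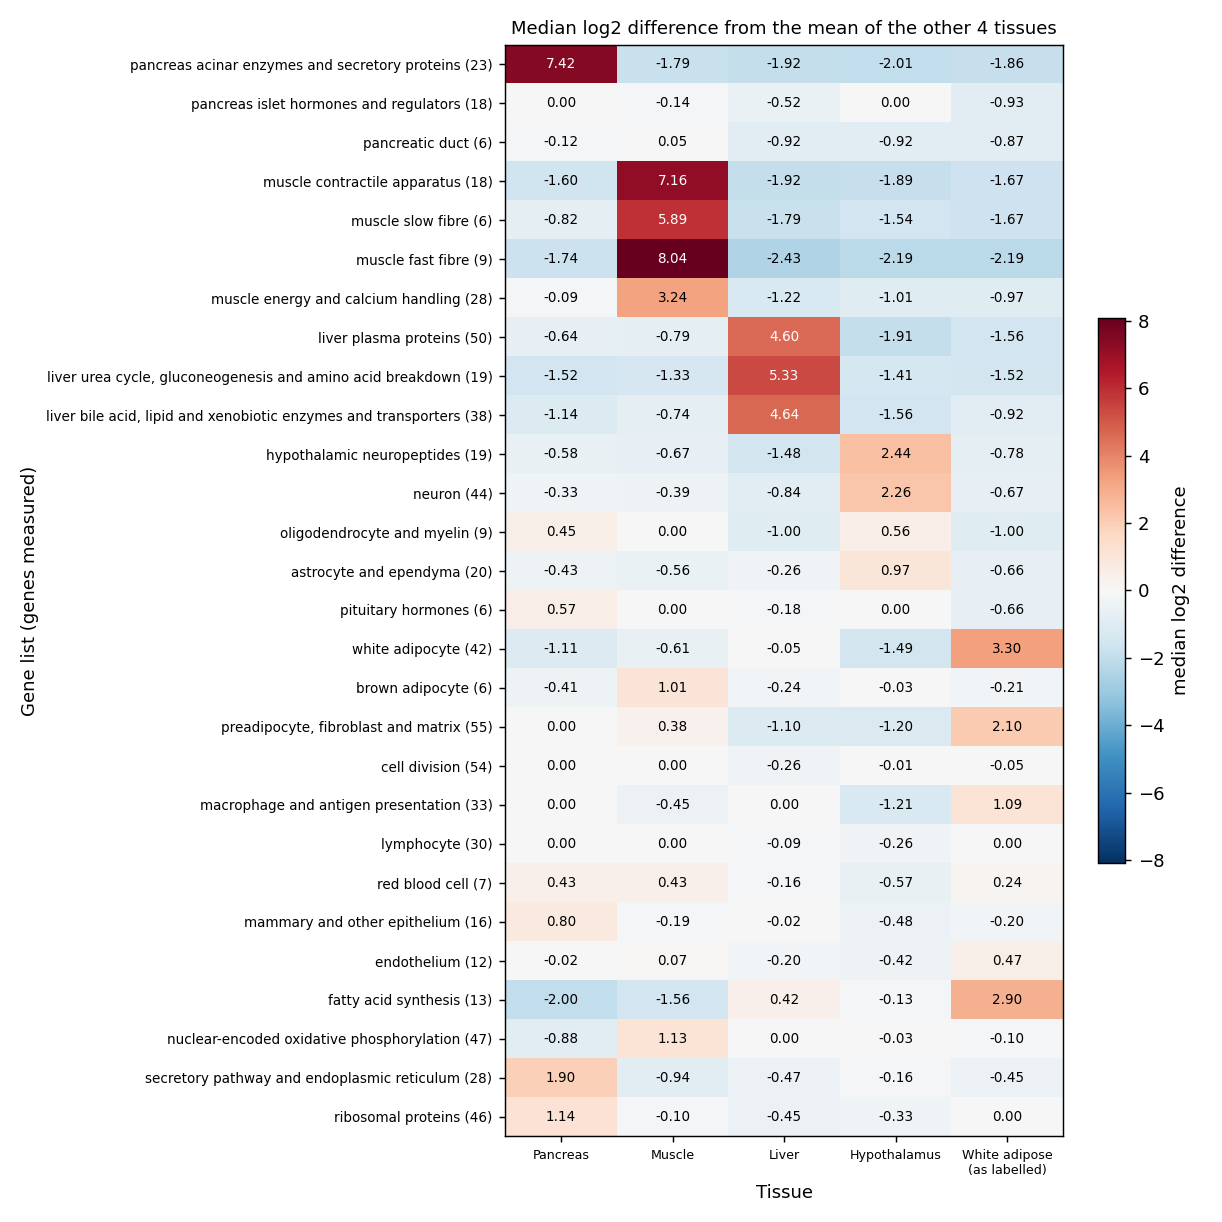
Each cell gives the median, over the genes of a list, of the log2 value in a tissue minus the mean log2 value of the other 4 tissues, in colour from blue (lower) to red (higher), with the number of genes measured beside each list. The lists of acinar enzymes in pancreas (7.42), fast fibre genes in muscle (8.04), urea cycle and related genes in liver (5.33), neuropeptides in hypothalamus (2.44) and white adipocyte genes in the adipose-labelled sample (3.30) have the highest value in their tissue.

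Across probe sets, which are not independent replicates, the tissues most alike were liver and the adipose-labelled sample, with a Spearman correlation of 0.728 averaged over the chips (Pearson 0.725), followed by hypothalamus and the adipose-labelled sample at 0.721 (Pearson 0.724). The order of these pairs was the reverse on chip B, at 0.735 and 0.746 (Pearson 0.742 and 0.752). Pancreas and hypothalamus were least alike, at 0.529 (Pearson 0.552). The other 7 of the 10 pairs lay between 0.561 and 0.660. Pairs with pancreas, whose arrays had the highest noise bounds, lay between 0.529 and 0.587. Those among liver, hypothalamus and the adipose-labelled sample, with the lowest bounds, lay between 0.654 and 0.728. Noise lowers a correlation, so this order does not separate likeness of tissues from noise of arrays. In all, 330 probe sets were high in both tissues of a pair, at least 4 times the highest of the other 3. Liver and the adipose-labelled sample shared 66, of which 60 had both values above noise. Cyp2e1, a cytochrome P450, read 16351 in liver and 17182 in the adipose-labelled sample, at least 14.0-fold above the other 3 tissues, and Gsta3, a glutathione transferase, at least 3.72-fold. Igfbp4, a binding protein of insulin-like growth factors, read 5952 and 2315 in the same tissues, but its other probe set also read 2329 in muscle, against 2946 in the adipose-labelled sample. Hypothalamus and the adipose-labelled sample shared 28 probe sets, 22 with both values above noise. Nnat, neuronatin, read 7707 in hypothalamus and 5202 in the adipose-labelled sample (at least 4.46-fold), Pygb, the brain form of glycogen phosphorylase, 3262 and 3272 (at least 1.25-fold), and Gnb2, a G protein subunit, 6677 and 1964. Pancreas and liver shared 43, and 21 with both above noise, among them the lipoprotein gene Apom (at least 3.88-fold) and the keratin Krt8 (at least 1.70-fold). Hamp, which encodes the iron hormone hepcidin, read 20882 in liver and 1610 in pancreas, the latter below noise. Pancreas and muscle shared the most, 75, but 22 with both values above noise and 24 with 75th percentile scaling. Mef2c, a transcription factor of muscle, read 3659 in pancreas and 3984 in muscle (at least 9.38-fold), but its chip B probe set read -692 in pancreas and 1841 in muscle. Hes3, a transcription factor of the Hes family, was at least 3.39-fold higher in this pair by its chip B probe set but below noise in both tissues by its chip A probe set, and Top3b, a topoisomerase, read 2536 in pancreas, below noise. The remaining 6 pairs shared between 10 and 26.

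Genes often used as references were not level across these tissues. Gapdh, of glycolysis, read 89568 in muscle and 6385 in pancreas on chip B, and 23722 in liver, and muscle was also highest by the 3' segment of the Gapdh control on both chips. Ppia, a cyclophilin, ranged from 5090 in muscle to 16013 in the adipose-labelled sample. Hprt, of purine salvage, read 1921 in hypothalamus, 889 in the adipose-labelled sample and below noise in pancreas and muscle, and Tbp was below noise in all 5. The 3 probe sets named Actb, of cytoplasmic actin, were all lower in muscle and the adipose-labelled sample, at 1300 and 1127 for the brightest, than in liver and hypothalamus, at 6775 and 7416. The 3' segment of the Actb control ran the other way in the deposited values, at 32570 in muscle and 17313 in the adipose-labelled sample against 2620 in liver and 3811 in hypothalamus on chip A. The ratio of its 3' over its 5' segment, a sign of RNA quality, was 4.74 for pancreas, 2.84 for liver, 2.17 for hypothalamus, 1.56 for the adipose-labelled sample and 1.41 for muscle on chip A. On chip B these ratios were 2.69, 2.61, 1.96, 1.51 and 1.34. By the ratio of the 3' over the middle segment muscle was instead the highest, at 5.03 on chip A and 4.94 on chip B, followed by pancreas at 3.31 and 3.09, since the 5' segment in muscle was brighter than the middle one. The ratios disagree for muscle, so they do not rank its RNA quality. The 3' over 5' ratio of the Gapdh control lay between 0.845 and 1.56. The chips share 61 control probe sets. Over those above noise, the log2 difference between the chips of a tissue had an SD of 0.28 (61 degrees of freedom), a factor of 1.21. This SD is of differences and not of single values, and lies around a mean difference per tissue of 0.38 to 0.73. Over the 3 or 4 per tissue that were bright on both chips, of 15 other shared probe sets, the SD was 0.37 (12 degrees of freedom), and both SDs cover hybridisation and not animals.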

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

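The alternatives that use noise bounds or spikes, or leave out the pancreas arrays, were chosen after seeing the data. The deposited values gave selective counts within 1.5 times of those reported for each tissue, and so did leaving out probe sets of relaxed design or the adipose-labelled sample. Scaling by the 75th percentile gave 297 for pancreas against 467. A floor at the 75th percentile gave 192 for pancreas, 139 for muscle, 126 for hypothalamus and 64 for the adipose-labelled sample, against 467, 241, 258 and 119. The 2-fold rule gave 1398, 901, 506, 686 and 348 for pancreas, muscle, liver, hypothalamus and the adipose-labelled sample, the 8-fold rule 164, 108, 162, 104 and 47, and the mean of the other tissues as reference 1024, 580, 514, 561 and 376, as these thresholds are looser or stricter by construction. Requiring a value above noise gave 217 for pancreas, the noise bound of each array as floor gave 91, 98, 127, 47 and 32 in the same order, scaling by spikes 67 for pancreas, 425 for hypothalamus and 194 for the adipose-labelled sample, and leaving out the pancreas arrays 411 for muscle. The 330 shared probe sets became 105 with the higher floor, 1574 with the 2-fold and 72 with the 8-fold rule, and 187 with both values above noise. The mean correlation over the 10 pairs, 0.618, was 0.559 with the higher floor and 0.602 without probe sets of relaxed design. The medians of 5 lists, each in its own tissue, stayed above 0 under the alternatives run: acinar genes 7.01 with quantile normalization and 6.18 with the higher floor, contractile genes 6.57 and 5.53 likewise and 7.51 without pancreas, plasma proteins 5.04 with 75th percentile scaling, 3.64 with the higher floor and 4.89 without pancreas, neuron genes 0.41 and white adipocyte genes 2.35 with the higher floor. The brown adipocyte list in muscle, of 6 genes, turned to -0.060 without probe sets of relaxed design. In all, list medians moved by more than the technical SD in 55 cases and by less in 161, and values of named genes in 171 and 217, with no other reversal. That SD, 0.28, is of differences between chips over bright controls, so it may not hold for dim genes. Where the construction does not show it, the cause was not tested. Of 97 named genes called for a tissue, 97 kept a 4-fold difference in the deposited values, 94 with 75th percentile scaling, 95 with quantile normalization and 83 with the higher floor. The planned floor at the 25th percentile was not run, since that value is negative on chip B and has no logarithm. The background limits the calls: 8.36% to 41.1% of an array's probe sets lay above its noise bound.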

Other observations

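The tests on scaling by spikes, on other probe sets of a gene and on Alb were chosen only after the result, or part of it, was seen. A control for pyruvate carboxylase, not described so far, differed between tissues in the deposited values. Its 3' segment, of an enzyme that feeds both gluconeogenesis and fat synthesis, read 11090 on chip A and 15107 on chip B in the adipose-labelled sample, 2945 and 6180 in liver, and at most 1067 in the other 3 tissues. The 5' segment of the Actb control in muscle was 3.56 times its middle segment on chip A and 3.70 times on chip B, against 0.700 to 1.15 in the other tissues.

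The title of the adipose-labelled sample names an adult mouse and a preconfluent state. That state would fit a culture of dividing precursor cells rather than tissue. The tables argue against that: the white adipocyte list had a median of 3.30 and stayed at 2.35 or above under every alternative run, the cell division list had a median of -0.049, and all 3 measured of the 5 fat cell genes fixed for the test (Adipoq, Retn and Lep) were called. The list of preadipocytes, fibroblasts and matrix was raised as well, with a median of 2.10 (percentile 100). By itself that list does not speak against precursor cells. A culture without blood or immune cells would lack macrophage genes, and their median of 1.09 met the mark set beforehand against that. It does not settle the question, since it rests on dim genes. The median was 0.041 with the floor at the 75th percentile, which levels dim genes by construction. Of 33 macrophage genes 2 were called, both under the pancreas noise bound. The lymphocyte list had a median of -0.0023 here and the red blood cell list 0.24, with no gene called in this sample. A culture that held blood or immune cells was not tested. That the sample is white adipose tissue, as its source label says, remains a hypothesis.

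Pancreas had the most selective probe sets, 467, and 330 of them were on chip B. Its arrays had the widest spread below 0, and 46.5% of the calls lay above the noise bound, a share small enough to meet a mark of noise set before it was counted, but on a bound chosen after the data were seen. Turning the sign of the pancreas values gave 693 calls against 467 (465 against 241 for muscle). More calls with the sign turned than without it mean that noise was not symmetric about 0, so this count does not estimate the share of noise. With the noise bound of each array as floor pancreas had 91 calls and liver 127. The hybridisation spikes were 3.99 times as bright on chip A and 4.74 times on chip B as the median of the other tissues. When arrays were scaled by them 14.3% of the calls remained, a loss that this ratio fixes. With quantile normalization pancreas still had the most calls, 349 against 288 for liver (297 against 328 with 75th percentile scaling). Quantile normalization gives every array the same distribution of values. It can thus lift an array with few expressed genes too, and it cannot decide the question. Whether the scaling up of such arrays made the excess is left open. Background noise may account for part of it, but for 15 of 29 calls below noise (51.7%) at least 50% of the gene's other probe sets were highest in pancreas, against 26.5% of probe sets not called and 33.9% of those highest in pancreas but below noise, which leaves a tissue difference open for part of them. Of pancreas calls above noise the same held for 26 of 41 (63.4%). In muscle, also with high noise bounds, it held for 4 of 10 calls below noise (40%). Among uncalled probe sets highest in muscle but below noise it held for 39.3%, so muscle showed no such excess. A gene's other probe sets were read on the same arrays, so they are not independent support.

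Alb read 26266 in pancreas on chip B, 1.45 times its value in liver, and 8226 in muscle, both above the noise bound. It read 150 in hypothalamus and 183 in the adipose-labelled sample, below their noise bounds. Liver RNA as the source of this signal in pancreas is argued against by 40 other plasma protein genes, chosen as bright in liver whatever their value in pancreas: their values in pancreas were a median of 0.0445 times those in liver, and at most 0.482 times, although 9 were above noise in pancreas, so a smaller share of liver RNA stays open. With arrays scaled by the spikes Alb in pancreas was 0.346 times its value in liver, as the ratio of the spikes fixes. With quantile normalization it was 1.52 times, but this gives every array the same distribution and cannot decide the question. The part of scaling in the order of these tissues is left open. A factor for a whole array moves signal and noise alike, so it does not make a signal 10.1 times the noise bound in pancreas or 5.02 times in muscle. That probe set is of a family design, so binding of other messages is open and was not tested.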
